A study of Mus musculus with 28 samples.

How the data were processed

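RNA sequencing libraries were made from microglia and astrocytes of 14 mice, sorted from each brain with antibodies against CD11b and ACSA-2 respectively, which gave 28 libraries. All mice were labelled APOE4fl/fl, with a knocked-in human APOE4 gene flanked by loxP sites on both alleles. Some carried the APPPS1 transgenes, which drive amyloid plaque formation, and some carried a tamoxifen-inducible Cre under the Aldh1l1 promoter, which is active in astrocytes. All mice received tamoxifen at 3.8 months of age, as 2 doses of 100 mg per kg, and cells were collected 10 days later. Per the labels, each cell type had 5 APPPS1 Cre-negative, 5 APPPS1 Cre-positive, 2 amyloid-free Cre-negative and 2 amyloid-free Cre-positive libraries. The series description gives 4 mice for each APPPS1 group, so the count of 5 was taken from the sample labels. Which exons lie between the loxP sites was not stated.

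The deposited table holds raw counts per gene. Per the labels, reads were demultiplexed with bcl2fastq, aligned with STAR and counted with featureCounts of Subread, with the builds GRCm38 and GRCh38. No settings or releases of these tools were given. The table held 95966 rows of mouse and human genes. Of its gene IDs, 258 stood on more than 1 row with identical counts and were kept once. This left 40481 mouse and 55093 human genes. Positions came from GENCODE M21 on GRCm38, which matched 40254 of the mouse gene IDs. Total counts per library ran from 26162612 to 63802747. Human genes took from 0.0420% to 0.237% of the counts. Libraries of 1 group varied far more than counting error, with a chi-square per degree of freedom of at least 43.9, so the spread between mice, not depth, set the precision. A count of 0 was read as an upper limit of 3 counts. Such limits cover counting error only, because the reads carry no molecular identifiers.

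Mouse genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by group with the tool's default rule, libraries were scaled with TMM, and quasi-likelihood F tests were run on a fit with 1 term per genotype group. The 14 libraries of a cell type shared 1 fit. Comparisons between the cell types used 1 fit of all 28 libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene passed at an adjusted p under 0.05. Human genes were kept out of library sizes and of these tests, and were expressed as CPM, counts scaled by the mouse gene total of the same library. Human APOE, mouse Apoe, human APP, mouse App and Aldh1l1 were compared between Cre-positive and Cre-negative libraries by exact two-sided permutation tests, adjusted over the 14 tests of both cell types, of which 4 are not reported here.

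Lists of genes were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. They covered microglia identity, homeostatic microglia, early and late disease-associated microglia, type I interferon response, antigen presentation, inflammatory cytokines and chemokines, complement, lysosome and cathepsins, cholesterol synthesis, cholesterol efflux and lipoproteins, and fatty acid synthesis and oxidation. They also covered astrocyte identity, homeostatic astrocyte functions, pan-reactive, A1-type and A2-type reactive astrocytes, disease-associated astrocytes, amyloid processing and clearance, extracellular matrix, cell cycle, dissociation and immediate early genes, oxidative phosphorylation, glycolysis and hypoxia, mitochondrially encoded genes, and unfolded protein and oxidative stress. Markers of neurons, oligodendrocytes, their precursors, endothelium, pericytes and smooth muscle, ependyma and choroid plexus, border macrophages, monocytes and neutrophils, and lymphocytes completed the set. All 35 lists had at least 5 tested members in every comparison. Each was tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 35 lists of a comparison. Genes of a list were also adjusted over the list alone. Without mouse 459, 1 of the 35 lists passed camera with an estimated correlation, in 1 of the 12 comparisons, so list statements carry that value beside the preset one. With fry in 1 direction, 34 lists passed between the cell types, 18 for amyloid in microglia averaged over Cre and 2 in Cre-negative microglia. Another 6 passed for Cre in amyloid-free microglia, 1 for the microglial difference of the Cre effect, and 0 in each other comparison. An adjusted p given for a list without a name is from camera at the preset correlation. The text names the target genes, up to 12 of the largest changes per direction among genes that passed with a mean log2 CPM of at least 3, leaving out predicted genes and pseudogenes, and up to 4 members with the lowest p of each list described. Where fewer than 6 genes passed without mouse 459, the genes that complete the 6 of lowest p, with the same limit on the mean and the same gene types left out, are named as not passing. Other genes named are said to be chosen after their values were seen.

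The mouse number pairs the microglia and astrocyte libraries of 1 animal. As a check, residuals of the same mouse were correlated between the cell types over 16194 genes for 13 mice. The median correlation was 0.0121 within a mouse and 0.000312 between mice, and 2 of the 13 mice matched their own partner best. Fits with the mouse as a block are given where they changed a count by more than 1.5 times.

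The cell type genes of both libraries of mouse 459 went against their labels. Each comparison was therefore run on the libraries as labelled, which was the choice fixed beforehand, and again without both libraries of mouse 459, which was added after the data were seen. Counts of genes are given from both fits. Values of single genes and lists come from the fit without mouse 459 unless stated otherwise. List means per library, in the text and in the figures, use the scaling and gene filter of the fit as labelled. Alternatives to the settings were DESeq2 size factors in edgeR, no filter on low counts, human genes kept, limma voom with sample quality weights, the DESeq2 1.42.0 Wald test, sex-linked genes or markers of other cells as a covariate, 1 surrogate variable from sva 3.50.0, a fit of the 2 compared groups alone, the mouse as a block, and leaving out each library. Recovery was tested on simulated data, negative binomial counts drawn from each gene's mean, pooled over the genotype groups, and its dispersion. In these, 100 genes each were given 2-fold and 4-fold changes, drawn from genes with a mean log2 CPM of at least 3. Recovery shares hold for such genes, simulated independently of each other, and not for all genes tested. All changed genes stood in the same simulated set, which eases the adjusted threshold, so the shares can overstate recovery where few genes change. All libraries carried female Xist levels, so sex was not tested as a group.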

Results

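Gene counts were available for microglia and astrocytes sorted from the brains of 14 mice, 28 libraries in all. In each cell type, 5 libraries came from APPPS1 Cre-negative mice, 5 from APPPS1 Cre-positive mice, 2 from amyloid-free Cre-negative mice and 2 from amyloid-free Cre-positive mice. APPPS1 mice carry transgenes that make them form amyloid plaques. Cre-positive mice carry a tamoxifen-inducible Cre that acts in astrocytes, where it removes a floxed human APOE4 gene. Total counts per library ran from 26162612 to 63802747. Errors are SD for levels. For log2 fold changes they are standard errors back-calculated as the absolute change over the square root of its F statistic.

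Both libraries of mouse 459, an APPPS1 Cre-positive animal, held the genes of the other cell type. Its library labelled astrocyte had a mean of 11.42 log2 CPM over the microglia identity genes and 0.96 over the astrocyte identity genes. Its library labelled microglia had 0.40 and 10.51 respectively. P2ry12, a purinergic receptor of microglia, stood at 7290 CPM in the library labelled astrocyte and at 15.9 CPM in the library labelled microglia. Each comparison was therefore made on the libraries as labelled and again without mouse 459, and values of single genes and lists come from the latter unless stated otherwise. List means per library come from the fit as labelled.

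**Figure D1:**
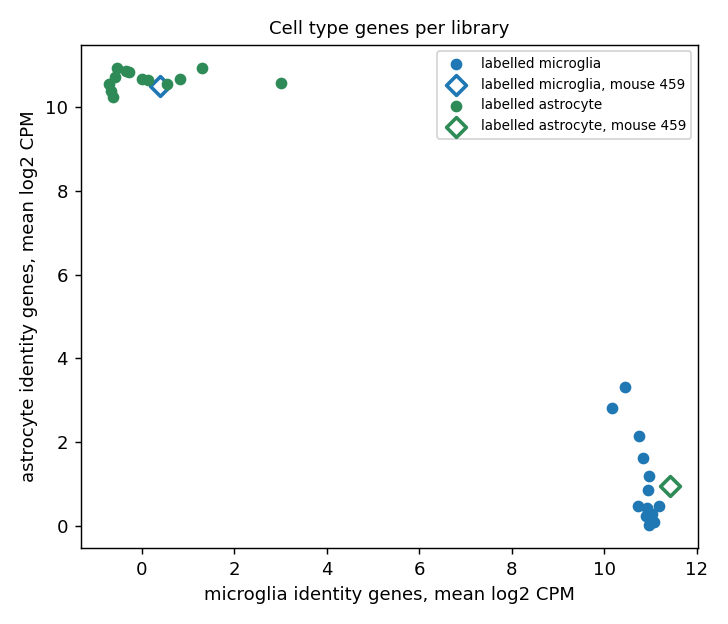
Mean log2 CPM of the astrocyte identity genes against that of the microglia identity genes, 1 point per library, coloured by its cell type label. The open diamonds are the libraries of mouse 459, which lie at 11.42 and 0.96 (labelled astrocyte) and at 0.40 and 10.51 (labelled microglia).

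The sorts were compared to check what each population contained. Microglia had far more Siglech, a sialic acid-binding lectin, with 1550 ± 225 CPM against 0.455 CPM in astrocytes, a log2 difference of 13.31. The lipid-sensing receptor Trem2 (12.31), the growth factor receptor Csf1r (12.07), the complement subunit C1qa (11.84) and P2ry12 (9.55) were higher as well. Astrocytes had more of the GABA transporter Slc6a11 (-11.98), the prosaposin receptor Gpr37l1 (-11.49), the neurotensin receptor Ntsr2 (-11.30), the gap junction protein Gja1 (-10.68) and the glutamate transporter Slc1a2 (-9.51). All 15 microglia identity genes and all 20 homeostatic microglia genes were higher in microglia, and all 16 astrocyte identity genes were higher in astrocytes. Of 25 cholesterol synthesis genes, 24 were lower in microglia, among them Msmo1 (-3.63), a sterol oxidase. These 4 lists passed camera with an adjusted p of at most 1.4e-05, and the lowest adjusted p of any list was 0.0656 with an estimated correlation. In all, edgeR called 16535 genes of 21612, 7646 higher in microglia and 8889 lower, and 15691 with the libraries as labelled. DESeq2 size factors moved the median log2 difference of all genes from -0.185 to -0.299.

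Human APOE counts were compared to see whether they fell with Cre. Which exons Cre removes was not stated, so counts that remain can come from exons left in place, and the ratio need not equal the share removed. In astrocytes of APPPS1 mice it stood at 620.5 ± 142 CPM in Cre-positive mice (n = 4) and at 1521 ± 225.7 CPM in Cre-negative mice (n = 5), a ratio of 0.408. With the library labelled astrocyte of mouse 459 the ratio was 0.441. The groups did not overlap, and the two-sided exact permutation p of 0.00794 was the smallest that either set of libraries can give. Adjusted over 14 tests it was 0.111, and 0.0556 as labelled. With these group sizes, a test can pass after adjustment only if several tests reach that smallest p, so failing to pass decides little here. In amyloid-free mice human APOE was 723 ± 286 CPM in Cre-positive and 1231 ± 254 CPM in Cre-negative astrocytes, n = 2 each, where an exact permutation test cannot go below 0.333. Mouse Apoe counts in APPPS1 astrocytes were 364 ± 66.6 CPM and 413 ± 34.5 CPM (exact permutation p = 0.206). How reads were assigned between mouse Apoe and human APOE is not given in the sources used here, so these counts need not stand for a mouse transcript. Aldh1l1, the folate enzyme whose promoter drives Cre, stood at 386.8 ± 14.6 CPM against 476.2 ± 46.7 CPM (exact permutation p = 0.0159, adjusted 0.111). In microglia human APOE was 781 ± 332 CPM in Cre-positive and 433 ± 292 CPM in Cre-negative APPPS1 mice (exact permutation p = 0.143), and mouse Apoe 219 ± 111 CPM and 116 ± 71 CPM (p = 0.119 by the same exact permutation). None of the target gene tests passed after adjustment, those of human APP and mouse App in either sort and of Aldh1l1 in microglia among them.

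**Figure D2:**
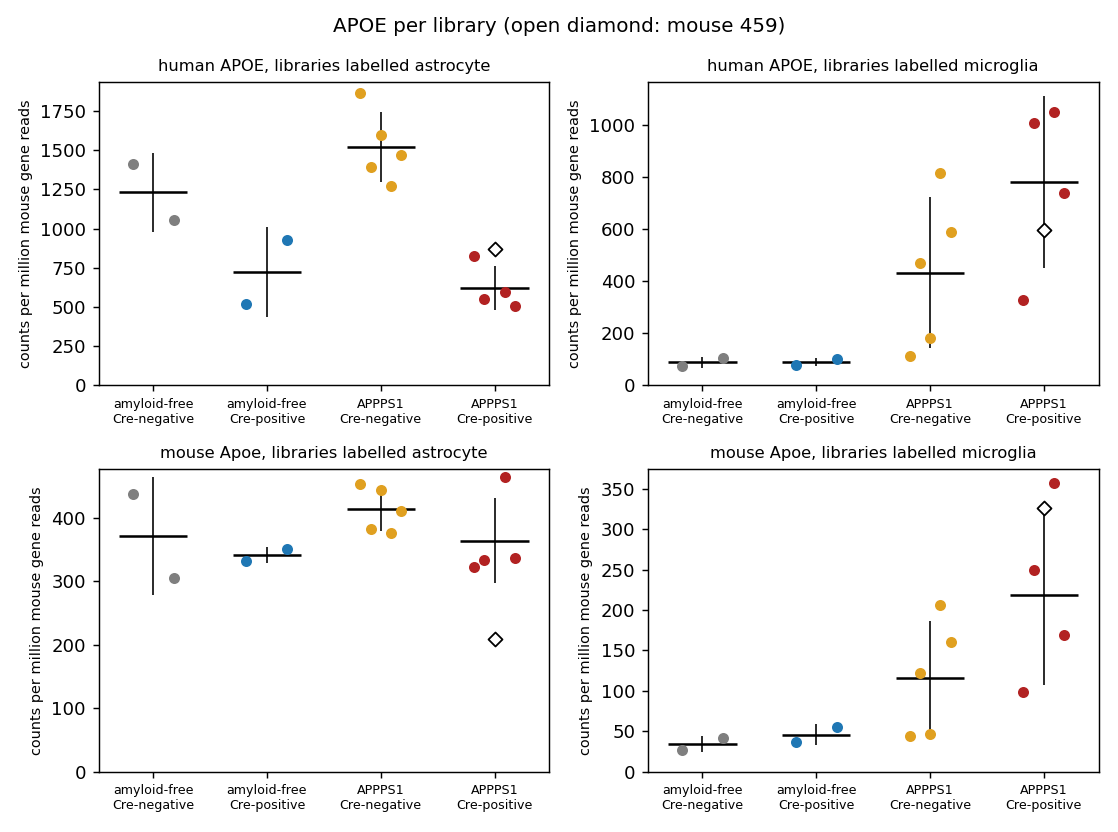
Human APOE and mouse Apoe in CPM of mouse gene reads, 1 point per library, with the group mean and SD without mouse 459, whose libraries are open diamonds under their label. Human APOE in APPPS1 astrocytes averaged 620.5 in Cre-positive and 1521 in Cre-negative mice, and in microglia 781 and 433.

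How microglia changed with amyloid was asked first over both Cre groups together. Averaged over Cre, the cystatin Cst7 rose from 10.6 ± 1.78 CPM (n = 4) to 1358 ± 706 CPM (n = 9), a log2 change of 7.01 ± 0.60 (adjusted p = 8.9e-05). It lies on chromosome 2 from 150570415 to 150578944. The glycoprotein Gpnmb (6.64), the growth factor Igf1 (4.92), osteopontin Spp1 (4.69), the checkpoint receptor Pdcd1 (4.53), the cholesterol 25-hydroxylase Ch25h (4.46), lipoprotein lipase Lpl (4.03) and the phagocytic receptor Axl (3.40) rose too. Of 25 late disease-associated microglia genes, 22 rose, and 24 adjusted over the list alone (camera adjusted p = 5.7e-49; adjusted p = 0.157 with an estimated correlation). Of 8 early genes, 7 rose, among them the signalling adaptor Tyrobp (1.29) and Ctsb (1.44), over all genes and over the list alone (1.0e-08; adjusted p = 0.157 with an estimated correlation). Lysosome genes rose in 17 of 22 cases, 18 over the list alone, with the proteases Ctsd (1.69) and Ctsz (1.55) and the hexosaminidase Hexa (1.46) among them (5.3e-21; adjusted p = 0.157 with an estimated correlation).

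Lists for division and metabolism were higher in the same microglia at the preset correlation, and none of them passed with an estimated one. Cell cycle genes rose in 21 of 24 cases, 23 over the list alone, including the mitotic kinase Cdk1 (2.37), the topoisomerase Top2a (2.31) and the tubulin regulator Stmn1 (1.66) (2.0e-25; adjusted p = 0.161 with an estimated correlation). In cholesterol synthesis 8 of 24 rose, 18 over the list alone, such as Fdps (1.51) and the demethylase Cyp51 (1.34) (3.4e-09; adjusted p = 0.243 with an estimated correlation). Glycolysis and hypoxia genes had 11 of 23 higher and 2 lower, with Gapdh (1.28) and Tpi1 (1.23) rising (4.7e-06; adjusted p = 0.161 with an estimated correlation), and oxidative phosphorylation 5 of 23, 12 over the list alone (3.8e-07; adjusted p = 0.243 with an estimated correlation). Microglia identity genes rose in 7 of 15 cases with a median of 0.40 (2.2e-06; adjusted p = 0.157 with an estimated correlation), complement genes in 3 of 13, the C1q subunits C1qa (0.64), C1qb (0.87) and C1qc (0.82) (0.027; adjusted p = 0.238 with an estimated correlation). Among 25 interferon response genes 5 rose, such as Ifit2 (1.33) and Bst2 (0.95) (0.0019; adjusted p = 0.483 with an estimated correlation), and homeostatic microglia genes rose in 3 of 20 cases (0.021; adjusted p = 0.483 with an estimated correlation). Among 18 antigen presentation genes 3 rose and 2 fell, the class II genes H2-Aa (-1.01) and H2-Eb1 (-0.96), and the list did not pass (0.314).

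The remaining lists were tested in the same microglia. Inflammatory genes rose in 4 of 21 cases, with Il12b (1.97) and the chemokine Ccl3 (1.43), at a median of -0.07, a mean of 0.12 and a list adjusted p of 0.152. Fatty acid genes had 3 higher and 1 lower of 24 (0.040; adjusted p = 0.347 with an estimated correlation). Lists that did not pass were amyloid processing and clearance (3 higher and 1 lower of 19, 0.060), cholesterol efflux (3 higher and 1 lower of 23, 0.751, median -0.20 and mean 0.09, with the lipoprotein Clu at -2.57), unfolded protein (3 of 19 higher, 0.182), mitochondrially encoded genes (0 of 13, with 3 lower over the list alone, 0.059) and extracellular matrix (3 higher and 6 lower of 17, 0.059). Immediate early genes fell in 5 of 23 cases, among them the transcription factor Klf2 (-1.92) (6.7e-04; adjusted p = 0.466 with an estimated correlation). Outside the lists, the kinase Pim1 and the transcription factor Cebpb each fell (-1.94). Klf2 was 26.7 ± 19.5 CPM in amyloid-free Cre-negative and 161.8 ± 107.5 CPM in amyloid-free Cre-positive microglia.

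Markers of some other cells were lower in APPPS1 microglia. Astrocyte identity genes were lower in 7 of 16 cases and higher in 1, 11 and 1 over the list alone, with Gja1 (-2.92) and Slc1a2 (-2.22) (1.4e-06; adjusted p = 0.157 with an estimated correlation). Their mean was 3.31 and 2.82 log2 CPM in mice 22 and 26, and at most 2.15 in the others. With the library labelled microglia of mouse 459 kept, Gja1 was at 2.47, Clu at 1.97 and Slc1a2 at 1.88. Endothelial markers fell in 6 of 14 cases, with the transporter Abcb1a (-1.67) and Ly6c1 (-1.40) (5.4e-06; adjusted p = 0.238 with an estimated correlation), and averaged 2.86 and 3.77 in mice 22 and 26 against at most 2.31 elsewhere. Lower members were also counted for homeostatic astrocyte functions (6 of 21, 1.9e-07; adjusted p = 0.157 with an estimated correlation), monocytes and neutrophils (2 of 14, 5.4e-04; adjusted p = 0.380 with an estimated correlation), neurons (3 of 16, 0.0094; adjusted p = 0.315 with an estimated correlation) and ependyma (1 of 9, 0.012; adjusted p = 0.243 with an estimated correlation). Pericyte (0 of 10, 0.051), lymphocyte (1 lower of 11, 0.097), border macrophage (2 lower of 10, 0.947) and oligodendrocyte markers (0 of 13, 0.863) did not pass.

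In all, 1066 genes were higher and 619 lower among 17593 (edgeR, 1685 genes), 669 of them beyond 2-fold, and 19 with the libraries as labelled. Without mouse 459, higher and lower genes numbered 990 and 845 by voom, 1735 and 987 by DESeq2, and 296 and 76 with 1 surrogate variable. The count was 2 with markers of other cells as a covariate, where Cst7 stood at 6.58, 372 with 1 surrogate variable and 2722 with DESeq2, and it was 1090 without mouse 774, 1022 without 475, 1013 without 458, 650 without 465, 392 without 759 and 432 without 26. As labelled, leaving out 1 microglia library gave 89 genes without mouse 469, 1685 without mouse 459 and 0 for each other library.

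**Figure D3:**
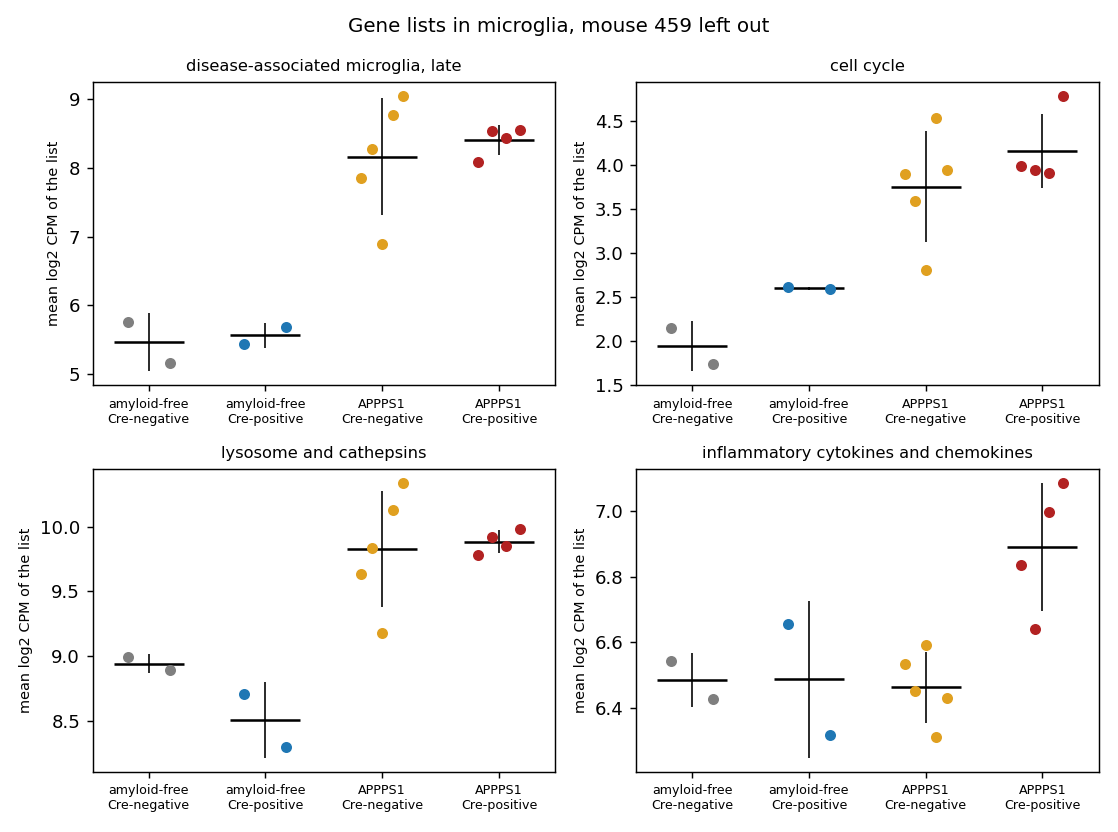
Mean log2 CPM of 4 gene lists in microglia, 1 point per library, with the group mean and SD. Values are scaled as in the fit as labelled, and mouse 459 is not shown. Late disease-associated genes lay at 5.17 to 5.77 in amyloid-free mice and at 6.89 to 9.04 in APPPS1 mice, of which Cre-positive mice spanned 8.09 to 8.56.

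The amyloid effect was also taken in Cre-negative mice alone, whose libraries are part of the comparison above. Cst7 rose from 9.18 ± 1.15 CPM (n = 2) to 1392 ± 982 CPM (n = 5), by 7.25 ± 0.86 on the log2 scale (adjusted p = 0.0053). Gpnmb (6.21), Spp1 (5.18), Pdcd1 (4.47), Lpl (4.33), Igf1 (4.32), Axl (3.53), the mineralisation regulator Ank (3.38) and the integrin Itgax (3.06) rose, as did the mitosis genes Cenpe (3.74), Mki67 (2.80) and Top2a (2.58). Lower were the adhesion molecule Vcam1 (-1.64), the glucocorticoid receptor chaperone Fkbp5 (-1.55) and the cytokine receptor Lifr (-1.47). Late disease-associated genes rose in 10 of 25 cases, 24 over the list alone (1.5e-49; adjusted p = 0.165 with an estimated correlation), and cell cycle genes in 3 of 24, 19 over the list alone (5.4e-29; adjusted p = 0.182 with an estimated correlation). Lysosome genes passed over the list alone in 13 of 22 cases (1.1e-13; adjusted p = 0.227 with an estimated correlation). Border macrophage markers, such as Cd163 (-1.76) and Cbr2 (-1.12), were lower over the list alone in 8 of 10 cases (3.0e-11; adjusted p = 0.120 with an estimated correlation). Over all genes 49 rose and 6 fell (55), and as labelled edgeR called 0, with 727 at an unadjusted p under 0.05, 7 by voom and 103 by DESeq2. Without mouse 459 voom gave 18, DESeq2 454, no filter 265 and a fit of the compared groups alone 0, and the count was 36 without mouse 774, 277 without 469, 32 without 447, 96 without 439, 0 without 465 and 1 without 759. Simulation of these groups without mouse 459 recovered 45% of 2-fold and 98% of 4-fold changes.

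Microglia of APPPS1 mice with and without the astrocytic Cre were compared next. A zinc finger gene, Zfp868 (ENSMUSG00000060427), rose from 19.7 ± 1.65 CPM (n = 5) to 94.3 ± 24.7 CPM (n = 4), by 2.26 ± 0.18 on the log2 scale (adjusted p = 4.4e-05). It lies on chromosome 8 from 69610857 to 69625548, while Apoe lies on chromosome 7. No other gene passed, and among genes that the naming rule covers the next lowest p belonged to the microRNA host gene Mir155hg (1.35) and the lysyl oxidase Loxl3 (-0.71), each at an adjusted p of 1. Inflammatory cytokines and chemokines stood higher as a list, with 18 of 21 positive, a median of 0.34, 0 past over all genes and 2, Cxcl1 and Il12b, over the list alone (8.6e-09; adjusted p = 0.124 with an estimated correlation). In this list Cxcl1, a neutrophil chemokine, was 28 ± 9.3 against 12.8 ± 5.5 CPM (1.13 ± 0.29), and Il12b differed by 1.12, the prostaglandin synthase Ptgs2 by 0.92 and Il1b by 0.88, each at an adjusted p of 1. Cxcl10, an interferon-induced chemokine, differed by 0.72 ± 0.17 (adjusted p = 1) and passed over the pan-reactive list alone (0.0014; adjusted p = 0.189 with an estimated correlation). Cell cycle genes were positive in 21 of 24 cases at a median of 0.38 (3.4e-05; adjusted p = 0.901 with an estimated correlation). Antigen presentation genes were negative in all but 3 of 18 cases, with H2-Aa at -0.93, H2-Ab1 at -0.80 and H2-Eb1 at -0.75 (3.4e-05; adjusted p = 0.548 with an estimated correlation). With fry, 0 of the 35 lists passed in this comparison, in 1 direction or in either. The lipoprotein genes Apoc2 (1.58 ± 0.42, 25.1 ± 12.3 against 8.40 ± 2.94 CPM) and Apoc1 (1.36 ± 0.43) did not pass over all genes, and Apoc2 passed over the efflux list alone.

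Homeostatic microglia genes had a median of -0.14 (0.037; adjusted p = 0.913 with an estimated correlation), and late disease-associated genes did not pass (0.108, median -0.03 and mean 0.04). Astrocyte identity genes had a median of -1.0 (0.0036; adjusted p = 0.901 with an estimated correlation) and oligodendrocyte markers -0.69 (0.0079; adjusted p = 0.901 with an estimated correlation). Monocyte and neutrophil markers passed as higher in camera at 0.050 although their median was -0.11 and their mean -0.07 (adjusted p = 0.901 with an estimated correlation). The count was 1 in both sets of libraries, of 18389 genes as labelled and 17593 without mouse 459, where 616 genes lay under an unadjusted p of 0.05. DESeq2 called 6 genes without mouse 459, 7 as labelled, and edgeR 2 without mouse 443. In simulated counts, 75% of 2-fold and 98% of 4-fold changes were recovered without mouse 459, and 7% and 76% as labelled. With many genes changed at once, these shares can overstate recovery in a comparison that called 1 gene.

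In amyloid-free microglia the same contrast rested on 2 against 2 mice. Zfp868 rose again, to 97.6 ± 23.8 from 26.6 ± 2.06 CPM (1.88 ± 0.26, adjusted p = 0.039), and Cbr2, a carbonyl reductase of border macrophages, fell from 34.0 ± 1.38 to 5.52 ± 2.35 CPM (-2.62 ± 0.34, adjusted p = 0.034). Next by p under the naming rule, and not past, were the chemokine receptor Cxcr4 (2.97), Fkbp5 (-1.96), the chemokine Pf4 (-2.02) and Rcan1 (-1.87), each at an adjusted p of 0.114. Border macrophage markers had 1 of 10 lower over all genes and 8 over the list alone, with Folr2 at -2.72 (7.1e-17; adjusted p = 0.101 with an estimated correlation). Homeostatic microglia genes were lower over the list alone in 7 of 20 cases (1.8e-09; adjusted p = 0.269 with an estimated correlation), with the adhesion ligand Selplg at -0.91. Endothelial markers were higher over the list alone in 8 of 14 cases, with Flt1 at 3.20 (1.2e-08; adjusted p = 0.238 with an estimated correlation), and astrocyte identity genes had a median of 1.88 (0.0034; adjusted p = 0.238 with an estimated correlation). The 2 called genes became 0 as labelled, where 932 lay under an unadjusted p of 0.05, voom called 0 and DESeq2 30. Without mouse 459 the count was 849 without mouse 22, 0 without 465, 1 without 759, 0 without 26, 146 with no filter, 0 by voom, 347 by DESeq2, 1 with human genes kept, 1 in a fit of the compared groups alone, and 0 with sex-linked genes or markers of other cells as a covariate. Of simulated 2-fold changes 22% were recovered without mouse 459, and of 4-fold ones 92%.

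Whether the Cre effect on microglia differed with amyloid was tested directly. Without mouse 459 border macrophage markers differed as a list, with a median of 2.34, 8 higher and 1 lower of 10 over the list alone and 0 over all genes (1.4e-21; adjusted p = 0.0371 with an estimated correlation). As labelled the list had an adjusted p of 0.011, and of 0.885 with an estimated correlation. Cbr2 had a difference of 2.82 ± 0.40 (adjusted p = 0.084), Cd163 of 3.29, Lyve1 of 3.33 and the folate receptor Folr2 of 3.06. Outside the list Gpx3 (2.66), Fkbp5 (2.18) and Rcan1 (2.06) were among the 6 of lowest p under the naming rule and did not pass. Border macrophage markers averaged 5.44 and 5.13 log2 CPM in amyloid-free Cre-negative mice 465 and 759, 3.73 and 2.96 in Cre-positive mice 22 and 26, and 4.02 to 4.70 in APPPS1 mice. Endothelial markers had a median difference of -1.85 (1.1e-09; adjusted p = 0.186 with an estimated correlation) and astrocyte identity genes of -2.69 (1.0e-05; adjusted p = 0.186 with an estimated correlation). No gene passed in edgeR, with 1527 at an unadjusted p under 0.05, 0 by voom and 51 by DESeq2, and as labelled 0, 575, 0 and 0 respectively. Without a filter 28 passed, and leaving out 1 library gave 107 without mouse 22, 3 without 469, 3 without 443 and 1 without 759. Recovery on simulated data without mouse 459 was 6% for 2-fold and 69% for 4-fold differences.

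In astrocytes of APPPS1 mice, the cells in which Cre acts, 2 genes rose with Cre. Apoc1 (ENSMUSG00000040564), an apolipoprotein gene next to Apoe on chromosome 7 from 19689481 to 19692660, rose from 16.9 ± 4.69 CPM (n = 5) to 70.7 ± 11.4 CPM (n = 4), by 2.06 ± 0.22 (adjusted p = 0.0028). Zfp868 rose from 27.8 ± 8.12 to 116 ± 17.3 CPM, by 2.06 ± 0.19 (adjusted p = 0.0013). Its chromosome 8 neighbour Mau2, a cohesin loader, stood at 0.90 and Fam13c at -0.78, each at an adjusted p of 0.055, and Ddx46 (0.66) and Tubb2b (-0.78) came next by the naming rule, each at 0.568. Cholesterol synthesis genes were negative in 24 of 25 cases with a median of -0.53, 0 past over all genes and 11 lower over the list alone (2.4e-19; adjusted p = 0.715 with an estimated correlation). The synthase Hmgcs1 was at -0.94, Fdps at -0.83, Fdft1 at -0.78 and the sterol sensor Insig1 at -0.78. Their mean was 5.65 to 5.93 log2 CPM in Cre-positive mice, 5.61 in Cre-negative mouse 439 and 6.23 to 6.72 in the other Cre-negative mice. Fatty acid genes were negative in 19 of 24 cases, with Elovl5 at -0.39 and Acly at -0.35 (6.0e-05; adjusted p = 0.481 with an estimated correlation). With fry, 0 of the 35 lists passed in 1 direction in this comparison, and 3 in either.

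Smaller shifts accompanied these astrocyte genes. Glycolysis genes had a median of -0.19 (9.2e-04; adjusted p = 0.801 with an estimated correlation), and astrocyte identity genes of -0.14 (0.0031; adjusted p = 0.801 with an estimated correlation), with Aldh1l1 at -0.35. Cell cycle genes (0.47, 0.0047; adjusted p = 0.801 with an estimated correlation) and ependymal markers (0.59, 0.0069; adjusted p = 0.715 with an estimated correlation) were higher. Markers of microglia and neutrophils stood apart in Cre-negative mouse 774, whose microglia identity mean was 3.02 log2 CPM against at most 1.30 elsewhere. The count was 2 of 20052 genes, and 1 as labelled, which was Zfp868. It was 10 with human genes kept, 36 by DESeq2 and 4 without mouse 439, and as labelled 2 with human genes kept, 3 by voom, 44 by DESeq2 and 10 with 1 surrogate variable. In simulated counts 68% of 2-fold and 98% of 4-fold changes were recovered without mouse 459, and 8% and 65% as labelled. With many genes changed at once, these shares can overstate recovery in a comparison that called so few.

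**Figure D4:**
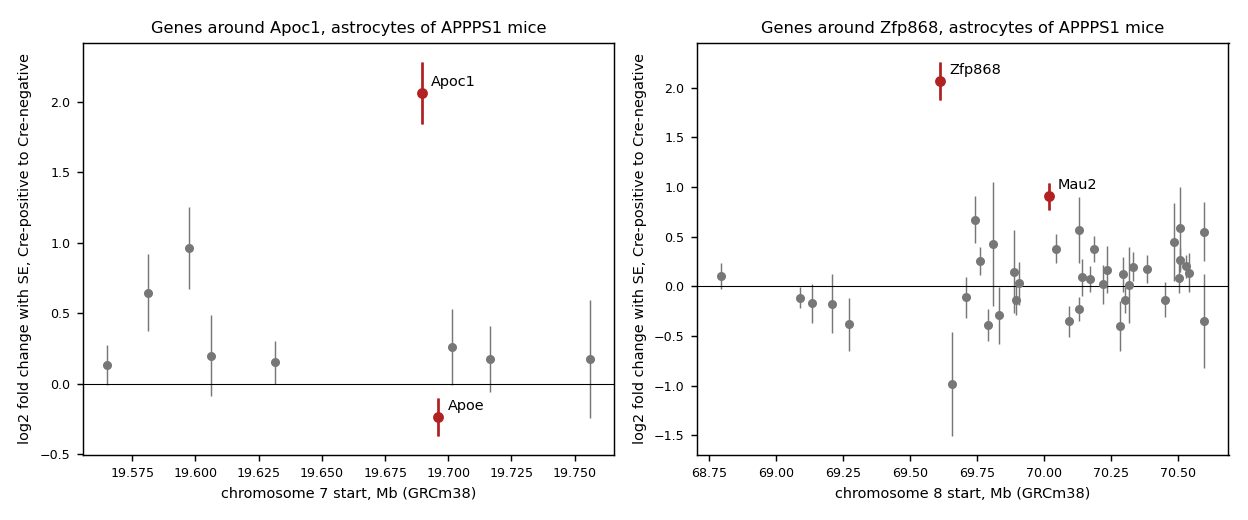
Log2 fold change with Cre, with standard errors, of genes around Apoc1 on chromosome 7 and around Zfp868 on chromosome 8 in astrocytes of APPPS1 mice without mouse 459, against the gene start in Mb, for genes with a mean log2 CPM of at least 0. Apoc1 and Zfp868 each reached 2.06, with Apoe at -0.23 and Mau2 at 0.90 among their neighbours.

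In amyloid-free astrocytes Cre-positive mice (n = 2) had fewer transcripts of several other brain cells than Cre-negative mice (n = 2). The ependymal gene Tmem212 fell from 96.2 ± 14.1 to 12.3 ± 1.92 CPM (-2.97). The endothelial surface gene Tm4sf1 (-2.79, adjusted p = 0.0078), the interferon-induced Ifitm3 (-2.76), the protease Ctsh (-2.67), the annexin Anxa2 (-2.50) and the chemoattractant Rarres2 (-1.57) fell. Zfp868 rose by 2.54 ± 0.30 (adjusted p = 0.010), along with the adhesion receptor Adgrb1 (1.42), Sned1 (1.29), Cit (1.09) and Gdpd2 (0.98), while Apoc1 was 34.8 against 12.1 CPM (1.53, adjusted p = 0.072). Endothelial markers were lower over the list alone in 12 of 14 cases and in 0 over all genes (6.4e-12; adjusted p = 0.455 with an estimated correlation), and ependymal markers in 2 of 10, 6 over the list alone (3.0e-09; adjusted p = 0.455 with an estimated correlation). Pericyte (median -2.97, 5.9e-06), oligodendrocyte (-1.71, 4.3e-06) and oligodendrocyte precursor markers (-2.40, 0.0010) were lower too, with an adjusted p of at least 0.455 with an estimated correlation for each. Astrocyte identity genes were higher over the list alone in 4 of 16 cases (2.3e-07; adjusted p = 0.455 with an estimated correlation). Of the 41 genes, 9 were higher and 32 lower, while voom called 72 higher and 70 lower and DESeq2 233 and 642. As labelled edgeR called 0, with 744 at an unadjusted p under 0.05, 4 by voom and 61 by DESeq2. The count was 0 without any of mice 759, 26 and 22, 141 without 465, 0 with markers of other cells as a covariate, with 1 surrogate variable or in a fit of the compared groups alone, 12 with sex-linked genes, 140 with no filter, 142 by voom and 875 by DESeq2. Simulation of these groups without mouse 459 recovered 22% of 2-fold and 83% of 4-fold changes.

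The Cre effect on astrocytes differed between APPPS1 and amyloid-free mice for 31 genes, 28 higher and 3 lower. Higher were Spp1 (6.12), the kinase Sgk1 (5.35), Tmem212 (3.56), Tm4sf1 (3.23, adjusted p = 0.0081), Ctsh (2.86) and the filament gene Vim (1.56), and lower Sned1 (-1.71), Disp3 (-1.62) and Gdpd2 (-1.28). Ependymal markers differed in 1 of 10 cases, 6 over the list alone (4.7e-11; adjusted p = 0.299 with an estimated correlation), endothelial markers in 12 of 14 over the list alone (3.1e-10; adjusted p = 0.546 with an estimated correlation), and astrocyte identity genes were lower in 6 of 16 over the list alone (9.1e-10; adjusted p = 0.353 with an estimated correlation). The endothelial mean was 2.29 and 2.49 log2 CPM in mice 22 and 26 and 3.30 to 5.85 elsewhere. As labelled edgeR called 0 (930 at an unadjusted p under 0.05, 0 by voom, 59 by DESeq2, 14 with 1 surrogate variable). Without mouse 459 the count was 0 with 1 surrogate variable, 1 with markers of other cells, 9 by voom, 103 with no filter and 577 by DESeq2, and it was 0 without any of mice 759, 26 and 22, 1 without 469, 779 or 475, 2 without 443, 3 without 447, 18 without 465, 65 without 460 and 92 without 439. Of simulated 2-fold differences 14% were recovered without mouse 459, and of 4-fold ones 76%.

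Reactive and interferon genes stood higher with amyloid in astrocytes as lists at the preset correlation, while no single gene passed in edgeR. No list passed with an estimated correlation, the lowest adjusted p being 0.120. With fry, 0 lists passed in 1 direction and 4 in either. Averaged over Cre, Gfap, the intermediate filament of reactive astrocytes, was 192.8 ± 46.2 CPM in APPPS1 mice (n = 9) and 75.3 ± 4.17 CPM in amyloid-free mice (n = 4), a log2 difference of 1.35 ± 0.19 (adjusted p = 0.17). The others of the 6 lowest p under the naming rule, each at the same adjusted p, were Ifit3 (0.996), Tm4sf1 (1.01), Ctsh (1.37), Paqr5 (1.62) and Pltp (1.09). Interferon response genes were positive in 24 of 25 cases with a median of 0.82, 0 past over all genes and 16 over the list alone (3.7e-19; adjusted p = 0.120 with an estimated correlation). Ifit3, an antiviral effector, was 72.0 ± 13.8 against 36.4 ± 7.98 CPM, and Usp18 differed by 1.43. Pan-reactive genes were positive in 13 of 13 cases, 3 over the list alone (5.3e-09; adjusted p = 0.120 with an estimated correlation), with Serpina3n at 1.06 and Vim at 0.66. Disease-associated astrocyte genes passed over the list alone in 6 of 23 cases (4.2e-10; adjusted p = 0.120 with an estimated correlation), A1-type genes in 6 of 11 (1.9e-08; adjusted p = 0.128 with an estimated correlation) and A2-type genes in 2 of 10 (2.8e-04; adjusted p = 0.269 with an estimated correlation). Endothelial markers were higher over the list alone in 12 of 14 cases (1.3e-16; adjusted p = 0.269 with an estimated correlation), with Cldn5 at 1.73, and cell cycle genes in 6 of 24 (4.1e-10; adjusted p = 0.269 with an estimated correlation). Cholesterol synthesis genes had a median of -0.31 (4.1e-10; adjusted p = 0.303 with an estimated correlation).

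The interferon mean was 0.36 and 1.48 log2 CPM in amyloid-free mice 22 and 26, 1.39 in 465 and 2.53 in 759, against 2.00 to 2.67 in APPPS1 mice. edgeR called 0 of 20052 genes, with 1409 at an unadjusted p under 0.05, 0 by voom and 254 by DESeq2, and as labelled 0, with 656, 0 and 36. Without a filter 1 passed, and leaving out mouse 460 gave 2 and mouse 458 gave 1. In Cre-negative mice alone Gfap was 198.6 ± 40.4 CPM (n = 5) against 77.4 ± 4.14 CPM (n = 2), a difference of 1.36 ± 0.27, and Serpina3n differed by 1.47. By the naming rule the lowest p belonged to Cit (0.94), Sned1 (1.17) and Rasgrf1 (1.249), with Gfap, Sgk1 (-2.80) and Chil1 (0.60) after them, none past the threshold. Disease-associated astrocyte genes passed in 2 cases over the list alone (1.7e-06; adjusted p = 0.525 with an estimated correlation), and microglia identity genes had a median of 1.80 (2.8e-04; adjusted p = 0.538 with an estimated correlation), in a group that holds mouse 774, which stood apart in these genes at 3.02 log2 CPM. There edgeR called 0, with 815 at an unadjusted p under 0.05, 0 by voom and 19 by DESeq2, and as labelled 0, 231, 0 and 0. In simulated counts without mouse 459, 80% of 2-fold and 100% of 4-fold changes were recovered for amyloid averaged over Cre. In Cre-negative mice alone the shares were 44% and 92%. With many genes changed at once, these shares can overstate recovery in comparisons that called 0 genes.

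**Figure D5:**
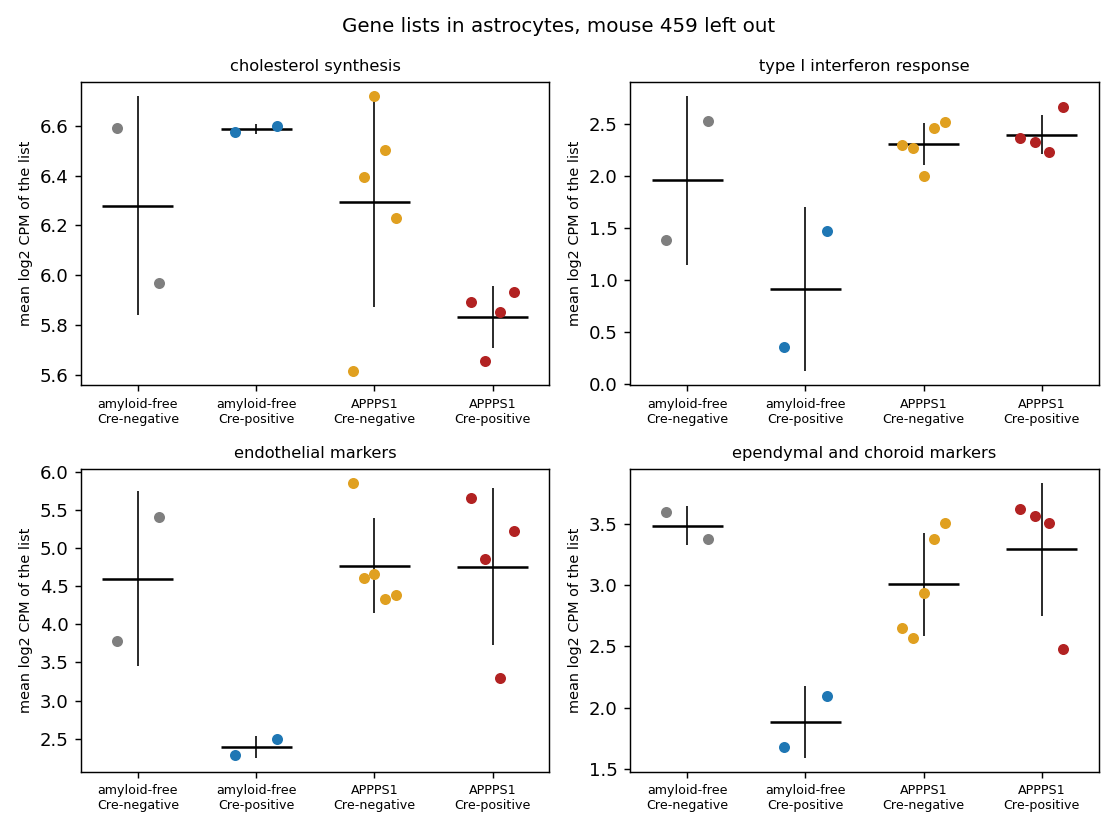
Mean log2 CPM of 4 gene lists in astrocytes, 1 point per library, with the group mean and SD. Values are scaled as in the fit as labelled, and mouse 459 is not shown. Cholesterol synthesis genes lay at 5.65 to 5.93 in APPPS1 Cre-positive mice, and endothelial markers at 2.29 and 2.49 in amyloid-free Cre-positive mice against 3.30 to 5.85 in the others.

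The Cre effect in APPPS1 mice was compared between the sorts. Tmie, an inner-ear mechanotransduction gene, passed (adjusted p = 0.0289), and it was named after its values were seen. It stood at 9.02 ± 1.05 CPM in Cre-negative and 9.53 ± 1.93 CPM in Cre-positive astrocytes. It had 0 counts in the 4 Cre-positive microglia libraries and 0.056 to 0.229 CPM in the 5 Cre-negative ones. Amyloid-free microglia averaged 0.0132 CPM in Cre-negative and 0.0709 CPM in Cre-positive mice. With a 0 read as an upper limit of 3 counts, these microglial values lie near the floor. Monocyte and neutrophil markers differed as a list (2.0e-06; adjusted p = 0.971 with an estimated correlation), with S100a8 at 184 CPM in the astrocyte library of mouse 774 and at most 0.295 CPM in the other 12 astrocyte libraries. The blood adaptor gene Lcp2 differed by 3.92 (adjusted p = 0.30) and Tmem119 by 3.01, and Tyk2 (-1.04), Phka2 (-0.96), Ddx46 (-0.66) and Ndor1 (-0.66) lay between them by p under the naming rule. The count was 1 with edgeR, 0 with the mouse as a block, 0 by voom and 77 by DESeq2, and 0 without any of mice 439, 443, 447, 458, 460, 475 and 774 and 2 without 779. As labelled edgeR called 0, with 4530 at an unadjusted p under 0.05, 0 by voom and 1265 by DESeq2. Recovery on simulated data without mouse 459 was 22% for 2-fold and 89% for 4-fold differences.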

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

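The tests of explanations for mouse 459, Zfp868 and Apoc1 were chosen after these results were seen, while the counts over other splits of the libraries were planned.

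In both libraries of mouse 459, P2ry12, Aldh1l1, Cst7, S100a8 and human ESR1, the receptor part of the inducible Cre, lay on the side of the other cell type. All 62 identity gene values of the 2 libraries lay nearer to the mean of the other sort, which is consistent with exchanged cell type labels. The genes of the labelled cell type kept a median of at most 0.0607% of their usual level, which argues against a mixture of cells. Human ESR1 stood at 121 CPM in the library that held astrocyte genes, in the range of Cre-positive astrocytes, which argues against a Cre-negative animal. If the labels were exchanged, whether this arose at sorting, in library preparation or in the records stays open, and no biological explanation was tested.

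Zfp868 was higher in Cre-positive than in Cre-negative mice in both sorts and with and without amyloid. The sorts came from the same mice and are no independent support, and the amyloid-free groups held 2 mice each. Genes within 1 Mb of Zfp868 on chromosome 8 were set against windows across the genome. The share of windows whose genes differed with Cre as much was 0.00157 in microglia and 0.00650 in astrocytes. Near Zfp868, 11 of 48 genes in microglia and 8 of 50 in astrocytes had an unadjusted edgeR p under 0.05. This is in line with a chromosome segment that travels with the Cre transgene, a candidate explanation. Its log2 change of 2.26 ± 0.18 in microglia, where human ESR1 of the Cre averaged 0.672 CPM, argues against an effect of APOE removal inside astrocytes alone. An indirect effect of that removal on both cell types stays open and untested, because every Cre-positive mouse carried both.

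Apoc1, next to Apoe, was higher in Cre-positive astrocytes of APPPS1 mice. The 9 other tested genes within 100 kb of Apoe had a median log2 change of 0.178, with 2 of them at an unadjusted p under 0.05, both higher, by 0.65 and 0.96. These 2, Clasrp and Gm26890, overlap in position. Apoc2 and Cblc were negative, at a low mean log2 CPM of -3.18 and -1.78. Every other neighbour was positive, from 0.15 to 0.96. These values argue against a change of the whole neighbourhood by about as much as Apoc1, while a smaller rise of the neighbours stays open. Cre-positive APPPS1 microglia had at most 13.5 CPM of Apoc1 and Cre-positive APPPS1 astrocytes at least 48.45 CPM in the fit of both sorts, which argues against microglial RNA as the source. In microglia Apoc1 stood at 1.36 ± 0.43, more than 3 standard errors above no change though not past the test over all genes. Whether the rise in astrocytes needs the recombined cell stays open, since a rise in microglia can be separate from it. A variant of the locus carried by Cre-positive mice and a response to lower astrocytic APOE may each contribute, and both stay untested.

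A sample stood far from its group in 10 of 48 sets of 4 or 5 libraries, where chance gives about 1 in 20, and 7 of the 10 were mouse 459. As the gap over the range, its library labelled astrocyte gave 0.915 for Aldh1l1, 0.9991 for P2ry12, 0.796 for human ESR1, 0.9997 for Cst7 and 1.0 for S100a8. Its library labelled microglia gave 0.9973 for Aldh1l1 and 0.994 for human ESR1. S100a8, a neutrophil gene, gave 0.999 in the astrocyte library of mouse 774, at 184 CPM, and 0.925 in the microglia library of mouse 439, at 2113 CPM. Without mouse 459, mouse Apoe gave 0.899 in the Cre-positive astrocyte library of mouse 460.

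The Cre effect differed between APPPS1 and amyloid-free astrocytes for 31 genes without mouse 459, among them Tm4sf1, and this count was 0 without any of mice 759, 26 and 22, 1 without 469, 779 or 475, 2 without 443, 3 without 447, 18 without 465, 65 without 460 and 92 without 439. It differed between the sorts for 1 gene, Tmie, and for 0 without any of mice 439, 443, 447, 458, 460, 475 and 774 and 2 without 779. Border macrophage markers differed in their Cre effect between APPPS1 and amyloid-free microglia without mouse 459, an exclusion chosen after the data were seen, at an adjusted p of 0.0371 with an estimated correlation. As labelled the same value was 0.885.

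Counts of human genes that no comparison used also carried a signal. Human ESR1 averaged 99.7 ± 26.7 CPM in the 6 Cre-positive astrocyte libraries and was at most 0.0868 CPM in Cre-negative ones. Human GH1, a growth hormone gene, averaged 47.1 ± 14.6 CPM in the same libraries and was at most 0.521 CPM in Cre-negative ones. Its counts followed Cre as those of human ESR1 did, need not stand for a growth hormone transcript, and their source was not tested.

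Other splits of the same libraries were compared with the real one. For Cre in APPPS1 microglia, 3 of 100 splits called as many genes as the real 1 as labelled, the highest other also calling 1, and 4 of 100 without mouse 459, the highest other calling 9. For Cre in APPPS1 astrocytes 1 of 100 did as labelled, real 1 and highest other 0, and 2 of 100 without mouse 459, real 2 and highest other 4. Each share lay under 0.05. With real counts of 1 or 2, and other splits calling up to 9 genes, these shares do not exclude chance. What drove the split with 9 genes was not tested. For amyloid in microglia 1 of 100 splits, the real one, reached the real 1685 genes without mouse 459. The highest other called 0, which argues against chance. As labelled, 5 of 100 splits reached the real 19, and the highest other called 246, so chance was not excluded. For amyloid in astrocytes the real count was 0, which all 100 splits reach by construction in both sets of libraries, so this decides nothing about chance. The highest others called 165 as labelled and 116 without mouse 459, and what drove such splits was not tested. For microglia against astrocytes 1 of 30 splits reached the real count as labelled (15691, highest other 6689). Without mouse 459 it was also 1 of 30 (16535, highest other 7720). This is the smallest share that 30 splits can give, and it argues against chance. For the difference of the Cre effect between the sorts, 9 of 30 splits reached the real 1 without mouse 459, highest other 3, so chance was not excluded. As labelled the real count was 0, which all 30 splits reach by construction, highest other 1, and this decides nothing.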

How the results depend on the processing

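Leaving out mouse 459, with each alternative run again, and keeping it as labelled for single genes were chosen after seeing the data, and every other alternative was fixed beforehand. Counts came from edgeR unless another tool is named, and where they moved by more than 1.5 times the cause was not tested.

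DESeq2 moved most counts. In simulated counts for Cre in APPPS1 microglia without mouse 459 it made 36 false calls, where edgeR made 7 and voom 6. As labelled it gave 7 for Cre in APPPS1 microglia, 30 for Cre in amyloid-free microglia, 103 for amyloid in Cre-negative microglia and 922 for amyloid in all microglia. In astrocytes as labelled it gave 44 for Cre in APPPS1 mice, 61 for Cre in amyloid-free mice, 36 for amyloid and 59 for the difference of the Cre effect, and 1265 for its difference between the sorts. Without mouse 459 the same microglial comparisons gave 6, 347, 454 and 2722, with 51 for the difference. The astrocyte ones gave 36, 875, 254 and 577, with 19 for amyloid in Cre-negative mice, and the sorts differed in 77. Voom gave 7 and 1532 for amyloid in Cre-negative and all microglia and 3 and 4 for Cre in APPPS1 and amyloid-free astrocytes as labelled. Without mouse 459 it gave 0 for Cre in amyloid-free microglia, 18 for amyloid in Cre-negative microglia, 142 for Cre in amyloid-free astrocytes, 9 for the difference in astrocytes and 0 between the sorts.

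Covariates moved some counts. Markers of other cells gave 5 and 2251 for amyloid in Cre-negative and all microglia as labelled. Without mouse 459 they gave 0 for Cre in amyloid-free microglia, 2 for amyloid in microglia, 0 for Cre in amyloid-free astrocytes and 1 for the difference in astrocytes. A surrogate variable gave as labelled 37 and 1775 for those microglial amyloid comparisons, 10 and 2 for Cre in APPPS1 and amyloid-free astrocytes and 14 for the difference. Without mouse 459, 1 surrogate variable gave 372 for amyloid in microglia and 0 for both Cre in amyloid-free astrocytes and the difference. Sex-linked genes gave 0 for Cre in amyloid-free microglia and 12 for Cre in amyloid-free astrocytes. All libraries carried female Xist levels, at least 71.7 CPM, so this covariate does not separate sexes. The mouse as a block gave 0 between the sorts.

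With no filter, the counts without mouse 459 were 146 for Cre in amyloid-free microglia, 265 for amyloid in Cre-negative microglia, 28 for the microglial difference, 140 for Cre in amyloid-free astrocytes, 1 for amyloid in astrocytes and 103 for the astrocyte difference. Human genes kept gave 1 for Cre in amyloid-free microglia and 10 for Cre in APPPS1 astrocytes, 2 as labelled. The compared groups alone gave 1 for Cre in amyloid-free microglia in both sets, and 0 for amyloid in Cre-negative microglia and for Cre in amyloid-free astrocytes without mouse 459. Of the lists, 201 passed camera as labelled and 172 without mouse 459. With an estimated correlation 0 and 1 passed, with fry in 1 direction 33 and 61, and with fry in either direction 35 and 125.

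Leaving out each library gave as labelled 1 to 1 for Cre in APPPS1 microglia, 0 to 2 in amyloid-free microglia (2 without mouse 22), 0 to 0 for amyloid in Cre-negative microglia, 0 to 1685 in all microglia (89 without 469, 1685 without 459, 0 without each other) and 0 to 0 for the difference. In astrocytes it gave 1 to 2 for Cre in APPPS1 mice and 0 to 31 for the difference, the higher value without mouse 459, and 0 to 0 for the other comparisons. Microglia against astrocytes gave 14047 to 16535, its Cre difference 0 to 1 (1 without 459), and the human APOE ratio 0.408 to 0.468. Without mouse 459 the ranges were 1 to 2 for Cre in APPPS1 microglia (2 without 443), 0 to 849 in amyloid-free microglia (849 without 22, 0 without 465 or 26, 1 without 759), 0 to 277 for amyloid in Cre-negative microglia (36 without 774, 277 without 469, 32 without 447, 96 without 439, 0 without 465, 1 without 759), 392 to 2441 in all microglia (1090 without 774, 1022 without 475, 1013 without 458, 650 without 465, 392 without 759, 432 without 26) and 0 to 107 for the difference (107 without 22, 3 without 469 or 443, 1 without 759). In astrocytes they were 2 to 4 for Cre in APPPS1 mice (4 without 439), 0 to 141 in amyloid-free mice (141 without 465, 0 without 759, 26 or 22), 0 to 0 for amyloid in Cre-negative mice, 0 to 2 in all (2 without 460, 1 without 458) and 0 to 92 for the difference (0 without 759, 26 or 22, 1 without 469, 779 or 475, 2 without 443, 3 without 447, 18 without 465, 65 without 460, 92 without 439). Microglia against astrocytes gave 15554 to 16462, its Cre difference 0 to 2 (2 without 779, 0 without 439, 443, 447, 458, 460, 475 or 774), and the human APOE ratio 0.363 to 0.433. A lone library left in a group was assumed to vary like the others.

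Of 155 named gene results, 89 passed. Of their 1742 alternative values 1305 kept direction and call, 433 lost the call and 4 reversed. Of 1221 values of the others 1126 kept direction and stayed short of the threshold, 90 passed and 5 reversed. All 9 reversals came with mouse 459 kept as labelled, whose libraries held the other cell type: Clu at 1.97, Slc1a2 at 1.88 and Gja1 at 2.47 for amyloid in microglia, S100a8 at 2.95 for Cre in APPPS1 astrocytes, and Lcp2 at -4.79, Tmem119 at -8.04, Slc6a11 at 9.53, S100a8 at -3.32 and Tmie at 3.62 for the Cre difference between the sorts. Zfp868 stayed between 2.11 and 2.38 in APPPS1 microglia and between 1.96 and 2.21 in APPPS1 astrocytes and kept its call under each alternative tried there. In amyloid-free mice it stayed between 1.54 and 2.08 in microglia and between 2.31 and 2.68 in astrocytes. There it lost its call in each cell type under some alternatives. Spread between mice, not depth, limited these tests for all but low-count genes, which were not checked.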

Other observations

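The tests here were all chosen after the values were seen.

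Human APOE was higher in microglia of APPPS1 mice than of amyloid-free mice. It averaged 588 ± 343 CPM in 9 APPPS1 libraries and 87.9 ± 15.5 CPM in 4 amyloid-free libraries without mouse 459, a ratio of 6.69 (exact permutation p = 0.00280, adjusted over 4 tests 0.0112), and each APPPS1 library, from 110 CPM, lay above each amyloid-free one, up to 102 CPM. Mouse Apoe counts were 162 ± 101 CPM against 40.3 ± 11.8 CPM (exact permutation p = 0.0140, adjusted 0.0280), and they are no independent support, since how reads were assigned between the 2 genes is not given in the sources used here. In astrocytes human APOE was 1121 ± 508 CPM against 977 ± 367 CPM (exact permutation p = 0.632) and mouse Apoe 392 ± 54.2 CPM against 356 ± 56.9 CPM (exact permutation p = 0.288).

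Across the 9 APPPS1 microglia libraries, human APOE rose with the mean of the 25 late disease-associated genes, with a Pearson r of 0.739 (permutation p = 0.0396, adjusted over 2 relations 0.0444) and a Spearman rho of 0.667 (permutation p = 0.0589). Without the 2 libraries farthest from the median, 469 and 779, r was 0.892. It went against the mean of the 20 homeostatic microglia genes, with r = -0.730 (permutation p = 0.0444, adjusted 0.0444), rho = -0.800 (permutation p = 0.0138) and r = -0.665 without 458 and 469. With the means of the Cre-positive and Cre-negative groups removed, r was 0.754 (permutation p within the groups = 0.0566, adjusted 0.113) and -0.619 (permutation p within the groups = 0.126, adjusted 0.126). The pooled values are in line with the hypothesis that microglial APOE4 follows the disease-associated state across mice, and neither relation passed once the Cre groups were taken into account, so the hypothesis stays open.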
